A study of Mus musculus with 11 samples.

How the data were processed

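PolyA RNA from mouse bone marrow stromal cells, sorted by flow cytometry, was sequenced in 11 samples of 4 groups. The groups, taken from the sample labels, were 3 adult wild-type samples sorted as PDGFRa+CD51+, 3 perinatal wild-type samples sorted as PDGFRa+Sca1+, 2 perinatal wild-type samples sorted as PDGFRa+Sca1-, and 3 perinatal PDGFRa+Sca1+ samples with deletion of the insulin-like growth factor 1 receptor gene Igf1r. The sorted cell type labels call the perinatal wild-type cells postnatal and give no age for the knockouts. By their titles the PDGFRa+Sca1+ wild-type samples were Cre-negative and the knockouts Cre-positive, so any effect of Cre itself ran together with the deletion. PDGFRa and CD51 are surface proteins encoded by Pdgfra and Itgav, and Sca1 is the surface protein encoded by Ly6a. The labels do not say whether samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

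The authors deposited 3 tables, each for a different comparison, with raw counts per gene for every library. Reads were trimmed with Trimmomatic 0.32, the genome build was mm10 and DESeq2 was used, per the submitters' processing notes. The aligner, the read counter, the gene annotation and the strand setting are not given in the sources used here. TPM values of the adult and Sca1 tables were computed by the authors, per the file headers, and were used here only to compare columns between tables. The deposited knockout table also has columns headed TPM, but these held values on a log2 scale that went below 0 in 5 of the 6 libraries, with up to 301 such genes in a library, and entered no test. Each deposited table also holds a log2 fold change and an adjusted p-value from the authors' own DESeq2 comparison, per the file headers. The sign of the authors' log2 fold change was read from the counts in each table.

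Each table was analysed by itself, on the counts as deposited, because the tables were made separately. Of the gene identifiers, 16506 of 16507 in the adult table, 14267 of 14267 in the Sca1 table and 14910 of 14910 in the knockout table were found in GENCODE M21, whose assembly is the one named mm10, and gene coordinates are from that annotation. Total counts per library ran from 13412316 to 23782217. A count of 3, taken as the floor per library, corresponded to 0.126 to 0.224 CPM, or counts scaled to a common library total, and this floor covers counting error only. Libraries that appear in more than 1 table were compared gene by gene for equal counts.

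Genes were filtered with filterByExpr and libraries scaled with TMM factors. Groups were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest), with the group as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The families held 13757 genes for age, 13529 for the Sca1 gate and 13590 for the knockout. The standard error (SE) of a log2 fold change was its size divided by the square root of the quasi-likelihood F value. Group levels are the mean and standard deviation (SD) of TMM-scaled CPM, and levels of single libraries are counts or unscaled CPM. Fold changes of single genes at 0 in a whole group are given only as lower bounds against the floor of 3 counts per library. List medians use the fitted values of such genes, and where setting them at their bounds changed a median, that value is given beside it.

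Before the data were examined, 34 gene lists were fixed for stromal lineages, signalling and growth programmes, metabolism and other cell types of marrow and the tissue around it. The list for T and NK cells had fewer than 3 tested genes in every comparison and gave no test. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, and adjusted over the 33 lists of a comparison. The camera test was repeated with a correlation estimated for each list, which ended every camera call in all 3 comparisons. Bootstrap ranges of list medians are the central 95% of 10000 resamplings of the genes of a list, which are not independent replicates. Called members were counted over all genes tested and again with p-values adjusted over the list alone. Genes named in the text were also chosen by a rule fixed before the data were examined. The rule took the genes of the sort gates and the deleted receptor with Igf1 and Igf2, and the 8 called genes with the largest change per direction among those with a mean log2 CPM of at least 5 and no overlap between groups. It also took up to 4 called members of each list with the smallest adjusted p, or 2 abundant members where none was called. Names of predicted genes and pseudogenes were left out of the ranking. Other genes named below were chosen after their values were seen, and they are marked as such or stand as examples of a list. The text gives examples of the genes the rule took, and values of the others are not reported here.

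Fold changes of comparisons that share control libraries were compared across genes, beside the values from 20 simulations of unchanged groups measured against the same controls. The fits were tested on simulated data with the same libraries and 200 changed genes each. In the age design edgeR found 41% of genes changed 2-fold and 94% of those changed 4-fold. For the Sca1 design these shares were 29% and 92%, and for the knockout design 5% and 67.3%. False calls numbered 13 among 13543 genes, 15 among 13266 and 1 among 13357 in the same order. DESeq2 1.42.0 found 20% and 85.7% of the 2-fold and 4-fold changes in the knockout design, with 22 false calls. Of 20 simulated lists without change, camera called 1 in the age design and 0 in each of the other designs. Simulated genes varied independently of each other, so these counts give no rate of false calls for lists whose genes vary together. The estimated correlation was 0.797 for cartilage genes in the knockout comparison.

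Alternatives were RLE and upper quartile factors, no filter on low counts, DESeq2, limma-voom, counts thinned to the smallest library, the replicate number as a block, each library left out in turn, and fry or an estimated correlation in place of camera. Fits without the 2 perinatal libraries lowest in Ly6a, without genes at 0 in a whole group, and leaving out single libraries in the comparison of effects were added after seeing the data. Other splits of the libraries into 3 and 3 were fitted for the age and knockout comparisons.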

Results

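Bone marrow stromal cells of mice were sorted by flow cytometry and profiled by polyA RNA sequencing to ask how these cells differ with age, with Sca1 on the surface, and after loss of the receptor Igf1r. The 11 samples formed 4 groups: 3 adult wild-type samples (PDGFRa+CD51+), 3 perinatal wild-type samples labelled Sca1-positive, 2 perinatal wild-type samples labelled Sca1-negative (replicates 2 and 3), and 3 Sca1-positive samples with Igf1r deleted. Total counts were 17275839, 16976506 and 13412316 in the adult libraries and 14826303, 17325470 and 14458033 in the perinatal libraries of the same table. They were 15249175 and 13835467 in the libraries labelled Sca1-negative. In the knockout table the controls held 20276962, 17314226 and 14445537 counts and the knockouts 22187979, 18974296 and 23782217. The Sca1-positive wild-type replicates 2 and 3 were the same libraries in all 3 tables, with equal counts for 98.0% or more of the genes shared by the age and knockout tables. Replicate 1 was a different library in the age table and in the knockout table, with equal counts for 1.72% of genes.

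The deleted gene and the sorted marker were examined first, as a check of the labels. Igf1r (ENSMUSG00000005533, chromosome 7, 67952827 to 68233668, plus strand) encodes the receptor for insulin-like growth factors. Its counts were 599, 548 and 444 in control libraries 1, 2 and 3, and 182, 80 and 77 in the knockout libraries. The level was 30.3 ± 0.709 CPM (SD, n = 3) in controls and 5.18 ± 2.31 CPM (SD, n = 3) in knockouts, a log2 difference of -2.55 (SE 0.34), and all 3 knockout libraries lay below all 3 controls. The edgeR quasi-likelihood adjusted p was 0.0816, so Igf1r did not pass the threshold. It passed with DESeq2 (adjusted p = 3.95e-09), with thinned counts (edgeR adjusted p = 0.0476), without control 1 (0.0279) and without knockout 1 (0.0176). Igf1r did not pass without control 2 (edgeR adjusted p = 0.303), control 3 (0.382), knockout 2 (0.424) or knockout 3 (0.164). Against control 1 alone its log2 difference was -2.59. The counts are sums per gene and do not resolve the deleted exons.

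Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031, minus strand) ran against the Sca1 labels. The libraries labelled Sca1-negative held 10159 and 9112 counts, while the Sca1-positive libraries 2 and 3 held 239 and 145. The remaining libraries sorted as Sca1-positive were high, with 8624 counts in control 1 and 17051, 12936 and 22125 in the knockouts. Groups are therefore called by their labels below, and every direction between the libraries labelled Sca1-negative and Sca1-positive runs against what Ly6a shows. Ly6a is not listed under that name in the age table, so its level could not be checked there.

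**Figure D1:**
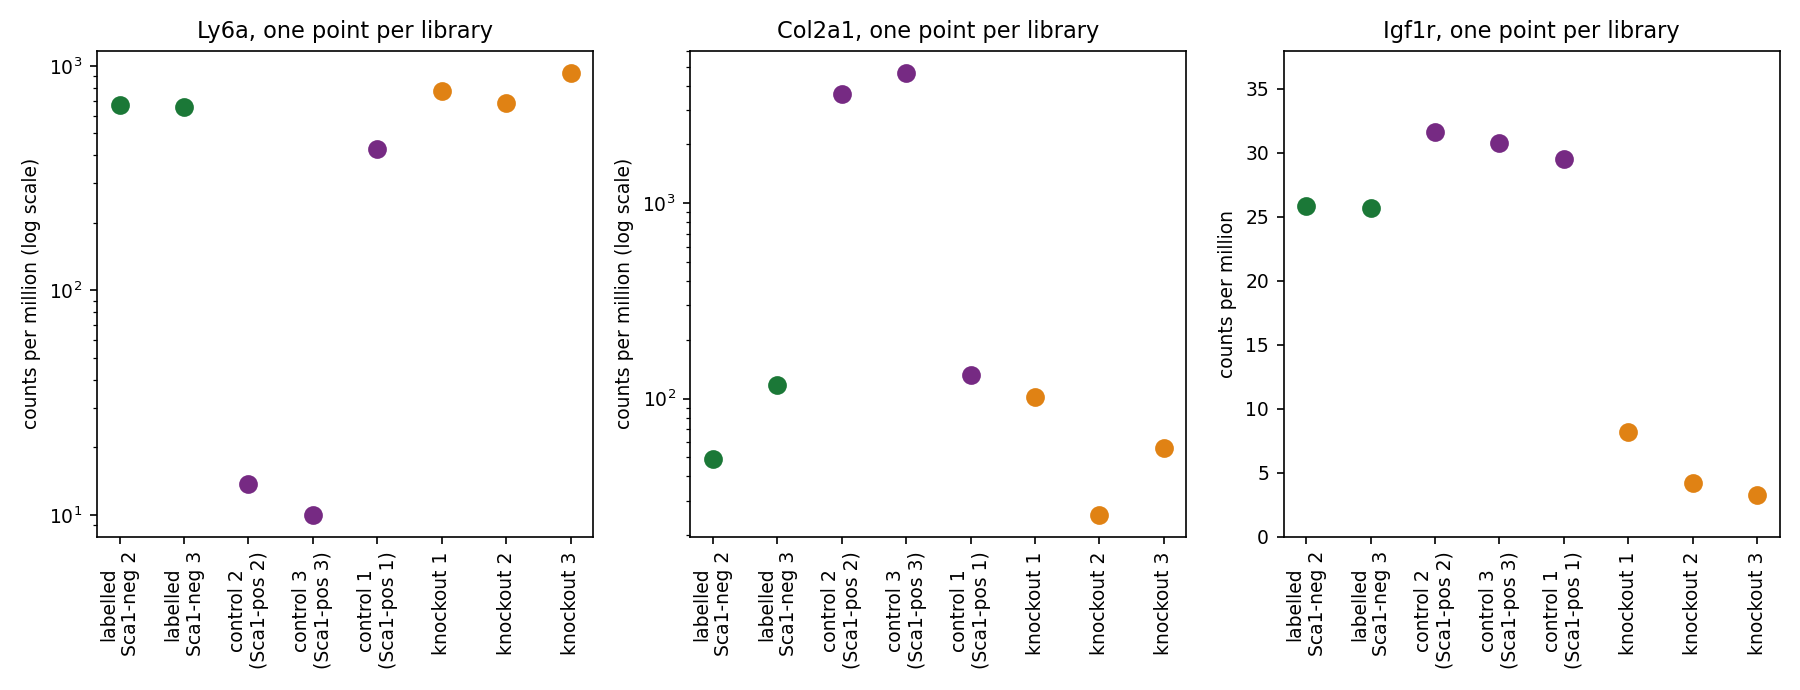
Unscaled CPM of Ly6a and Col2a1 (log axes) and of Igf1r (linear axis) in 8 perinatal libraries, with a point per library and colours for the 3 labelled groups. Ly6a was low and Col2a1 high in control libraries 2 and 3 alone, and Igf1r was lower in the 3 knockout libraries than in all others.

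Adult PDGFRa+CD51+ cells were compared with perinatal PDGFRa+Sca1+ cells to find how stromal cells change with age, and age and sort gate differed together in this comparison. The adult libraries were rich in monocyte and macrophage transcripts and poor in transcripts of the stromal, cartilage and bone lineages. All 15 tested genes of the macrophage list rose in adult cells. Lyz2, which encodes lysozyme (chromosome 10, 117277331 to 117282321, minus strand), was at 10949 ± 629 CPM in adult and 12.6 ± 0.501 CPM in perinatal libraries (SD, n = 3 each), a log2 fold change of 9.76 (SE 0.21). Pdgfra (chromosome 5, 75152292 to 75198215, plus strand), the gene of the receptor used to sort both groups, fell from 290 ± 29.7 to 13.1 ± 1.07 CPM (log2 fold change -4.47, SE 0.15, edgeR quasi-likelihood adjusted p = 6.54e-07). Itgav, the gene of CD51, rose by 2.27 on the log2 scale (SE 0.13, edgeR quasi-likelihood adjusted p = 3.69e-06). In total 5142 genes were higher and 5468 lower in adult cells among 13757 tested with edgeR's quasi-likelihood test. The authors' deposited table listed 5377 higher and 6041 lower, of which 5101 and 5309 were among these.

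Macrophage genes with the smallest adjusted p included Adgre1, which encodes the F4/80 antigen, at 863 ± 62.1 against 0.261 ± 0.119 CPM, Ctss at 1422 ± 116 against 0.650 ± 0.183 CPM and Cd14 at 299 ± 11.9 against 6.53 ± 1.15 CPM (SD, n = 3 each). The list took 2.58% to 2.81% of all counts in the adult libraries and 0.00335% to 0.00441% in the perinatal ones. Its camera adjusted p was 8.69e-08 (median log2 fold change 9.76), with an adjusted p of 0.279 with an estimated correlation. Other genes with large rises were Mpeg1, the gene of perforin-2, at 3235 ± 295 against 0.135 ± 0.127 CPM, and Cd5l, which is made by tissue macrophages and was at least 1546-fold higher, since all perinatal libraries listed it at 0. Arl11, Bcl2a1b, Cd300ld3, Cdkn2a and Lrch4 were likewise at 0 in all perinatal libraries and at least 513-fold, 863-fold, 629-fold, 465-fold and 436-fold higher in adult cells. All bounds against a group at 0 are uncertain, since the annotation and counting behind each library are not given in the sources used here. The 3 tested B lineage genes were higher in adult (Blnk, 93.0 ± 4.61 against 1.06 ± 0.677 CPM), but the list missed the threshold (camera adjusted p = 0.0554, and 0.366 with an estimated correlation) except with upper quartile factors (0.0456), and Ighm lost its call without perinatal replicate 2 (adjusted p = 0.0552) or adult replicate 2 (0.0557) in edgeR's quasi-likelihood test.

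Genes of the skeletal lineages fell. All 20 tested cartilage genes were lower in adult cells, also when adjusted over the list alone, with a median log2 fold change of -9.45, or -8.31 with the 6 genes at 0 in adult libraries set at their bounds (camera adjusted p = 0.00238, and 0.568 with an estimated correlation). The list took 0.105% of counts in perinatal replicate 1 and 0.836% and 0.933% in replicates 2 and 3, the libraries whose Ly6a ran against their label. Examples were Acan, the gene of aggrecan, at 0.0174 ± 0.0301 against 527 ± 268 CPM, and Sox9, at 7.23 ± 3.63 against 281 ± 173 CPM (SD, n = 3 each). Of 19 tested osteoblast and osteocyte genes 17 were lower, also when adjusted over the list alone (median -3.82, camera adjusted p = 9.26e-04, and 0.442 with an estimated correlation). Col1a1, the gene of a type I collagen chain, fell from 42664 ± 10182 to 1861 ± 524 CPM. Fibroblast progenitor genes were lower in 17 of 18 cases (median -6.94, camera adjusted p = 2.83e-04, and 0.442 with an estimated correlation), with Cd34 at 0.889 ± 0.298 against 601 ± 248 CPM. Matrix genes were lower in 21 of 25 cases and higher in 3 (median -3.76, camera adjusted p = 8.12e-05, and 0.366 with an estimated correlation). Dcn, the gene of decorin, and Mfap4 were among the lower ones. Thbs4, a matrix gene in tendon, was at 0 in all adult libraries and 2409 ± 333 CPM in perinatal ones, at least 13791-fold lower. Cnmd, Fxyd6 and Nrk were also at 0 in adult cells and at least 1885-fold, 1580-fold and 1400-fold lower, bounds with the same uncertainty. The marrow niche list was mixed, with 3 genes higher and 11 lower of 20, and was not called (median -1.39, camera adjusted p = 0.295), except without perinatal replicate 1 (median -1.60, camera adjusted p = 0.0403). Within it Lepr, the leptin receptor gene of adult marrow stroma, was at 0.503 ± 0.149 against 47.6 ± 12.4 CPM, while Gas6 rose by 2.22 and Grem1 by 4.54 on the log2 scale. Cxcl12, looked up after the other values were seen, was at 399 ± 144 CPM in adult and 457 ± 225 CPM in perinatal cells (SD, n = 3 each), a difference within the spread (edgeR quasi-likelihood adjusted p = 0.693).

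**Figure D2:**
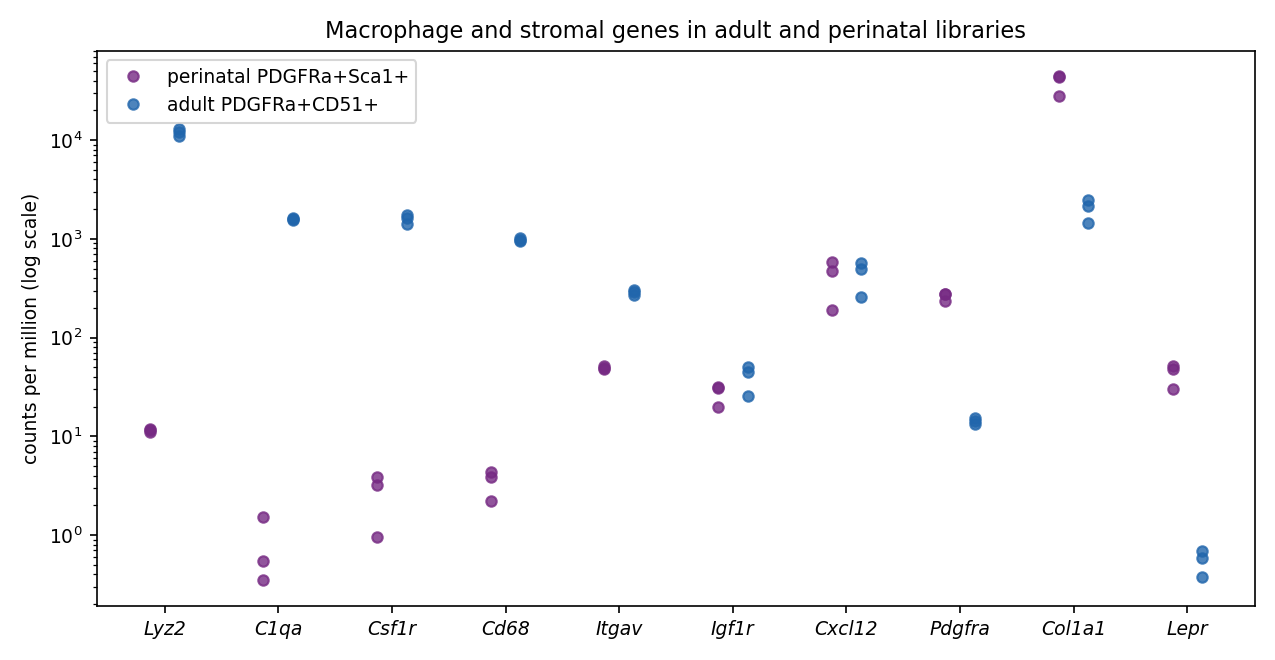
Unscaled CPM (log axis) of 10 genes in 3 adult and 3 perinatal libraries, with a point per library. Lyz2, C1qa, Csf1r and Cd68 were higher in every adult library, Pdgfra, Col1a1 and Lepr were lower in each, and the Cxcl12 and Igf1r points of the groups overlapped.

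Growth and cell cycle programmes were lower in the adult libraries, where age, sort gate, cell makeup and perhaps the counting of reads changed together. Insulin-like growth factor genes fell, with Igf2 (chromosome 7, 142650766 to 142666816, minus strand) at 15.1 ± 5.48 against 1952 ± 472 CPM (SD, n = 3 each; log2 fold change -7.02, SE 0.36) and Igf1 at 240 ± 53.6 against 660 ± 257 CPM (log2 fold change -1.46, SE 0.29, edgeR quasi-likelihood adjusted p = 0.00244). Igf1r itself was at 36.6 ± 12.5 CPM in adult and 30.2 ± 7.14 CPM in perinatal cells and did not pass the test (edgeR quasi-likelihood adjusted p = 0.412). Of 20 genes of the IGF axis 15 were lower and 4 higher (median -1.56, camera adjusted p = 0.00975), and Pappa, which encodes a protease of IGF-binding proteins, rose by 3.77 on the log2 scale. Imprinted growth genes were lower in 14 of 16 cases and higher in 2 (median -6.58, or -6.14 with 1 gene at its bound, camera adjusted p = 1.47e-04), with Dlk1 at 0.317 ± 0.188 against 1377 ± 179 CPM and Peg3 at 0.664 ± 0.0580 against 398 ± 5.28 CPM. All 20 mitosis genes and 17 of 21 DNA replication genes were lower (medians -1.87 and -1.45, camera adjusted p = 2.28e-05 and 1.40e-04), for example Birc5 at 7.55 ± 2.36 against 64.9 ± 2.33 CPM and Tyms at 13.4 ± 0.724 against 73.5 ± 11.5 CPM. Feedback targets of Hedgehog, Wnt and BMP signalling were lower in 16 of 18 cases (median -4.35, camera adjusted p = 3.92e-04), and limb and axial position genes in 19 of 23 (median -1.34, camera adjusted p = 3.34e-04). With an estimated correlation the adjusted p was 0.366 for the IGF axis, 0.253 for imprinted genes, 0.366 for mitosis, 0.356 for DNA replication, 0.442 for feedback targets and 0.279 for position genes. Counts adjusted over the list alone equalled those over all genes tested for all of these lists.

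Metabolic and stress programmes also differed between the adult and perinatal libraries, and for the same reason these differences cannot be assigned to age alone. Nuclear genes of the respiratory chain were lower in 23 of 25 cases (median -1.45, camera adjusted p = 1.70e-05), with Uqcrc1 at 133 ± 5.17 against 549 ± 9.14 CPM, and glycolysis genes were higher in 14 of 17 (median 1.29, camera adjusted p = 0.00258), with Pgk1 at 786 ± 36.5 against 254 ± 26.5 CPM (SD, n = 3 each). Of 25 ribosomal protein genes 16 were lower (median -0.61, camera adjusted p = 9.97e-04). The immediate early list, which also holds genes that respond to tissue dissociation, was lower in 19 of 20 cases (median -3.92, camera adjusted p = 7.77e-07), with Fos at 9.08 ± 1.53 against 4388 ± 687 CPM. Inflammatory genes were lower in 14 of 20 and higher in 2 (median -3.28, camera adjusted p = 0.00975), with Cxcl1 at 0.142 ± 0.163 against 771 ± 353 CPM. Interferon-stimulated genes were higher in 16 of 22 (median 1.70, camera adjusted p = 0.00125). Cell cycle inhibitor and p53 target genes were higher in 10 of 16 and lower in 3 (median 1.81, camera adjusted p = 0.0223, and 0.0557 without genes at 0 in a whole group). With an estimated correlation the adjusted p was 0.366 for the respiratory chain, 0.423 for glycolysis, 0.442 for ribosomal proteins, 0.279 for immediate early genes, 0.366 for inflammatory genes, 0.442 for interferon genes and 0.279 for the p53 list. For these lists too the counts adjusted over the list alone were the same numbers.

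A part of the adult differences involved genes at exactly 0 in every library of a group. With at least 50 counts in each library of the other group, 100 genes were at 0 in all adult libraries, 19 of them annotated pseudogenes, and 37 were at 0 in all perinatal libraries, 9 of them pseudogenes. Rps12, a ribosomal protein gene, was at 0 in the perinatal libraries and at 6147, 8089 and 5549 counts in the adult ones, while its near-identical copy Rps12l1 held 4721, 2395 and 1444 counts in the perinatal libraries and 0 in the adult ones. The values of such copies are uncertain, since the way shared reads were counted is not given. This applies also to the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, which were at 0 in all adult libraries and at least 2713-fold, 2890-fold, 1589-fold and 584-fold lower there. Without all genes at 0 in a whole group, 5114 genes were higher and 5162 lower. Whether annotation or counting differed between adult and perinatal libraries is not given. Such a difference could not be told apart from age in the remaining genes either.

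The libraries labelled Sca1-negative were compared with the libraries labelled Sca1-positive (2 against 2) to find what the marker separates among perinatal PDGFRa+ cells. Ly6a was 670 ± 22.1 CPM in the libraries labelled Sca1-negative and 11.8 ± 2.42 CPM in those labelled Sca1-positive (SD, n = 2 each), a log2 fold change of 5.83 (SE 0.26, edgeR quasi-likelihood adjusted p = 0.00147) that goes against the labels. Genes of fibroblast progenitors rose with it, and genes of cartilage and bone fell. Pdgfra did not pass the test at 332 ± 0.857 against 254 ± 33.7 CPM, and neither did Igf1r at 26.1 ± 0.776 against 30.8 ± 0.0877 CPM (edgeR quasi-likelihood adjusted p = 0.340 and 0.524). In all, 220 genes were higher and 377 lower in the libraries labelled Sca1-negative among 13529 tested. At an unadjusted p under 0.05 there were 1170 and 1393, where 676 are expected over both directions without any effect.

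Of 20 fibroblast progenitor genes 13 were higher in the libraries labelled Sca1-negative, and 18 when adjusted over the list alone (median 1.46, camera adjusted p = 4.46e-18, and 0.281 with an estimated correlation). Ly6c1, a neighbour of Ly6a on chromosome 15, was at 288 ± 12.9 against 11.3 ± 1.96 CPM and Dpp4, the gene of the surface peptidase CD26, at 62.2 ± 5.10 against 10.6 ± 1.14 CPM (SD, n = 2 each). Over all genes tested, rather than on this list alone, Pi16, Efemp1, Gap43, Tek and Mfap5 were among the largest rises. Their log2 fold changes were 2.99, 2.80, 2.60, 2.50 and 2.31. Efemp1 lost its call without labelled-negative replicate 2, where its log2 fold change was 2.97. Cartilage genes were lower in 19 of 21 cases over all genes tested and adjusted over the list alone (median -3.92, camera adjusted p = 2.39e-26, and 0.165 with an estimated correlation). Col2a1 (chromosome 15, 97975602 to 98004695, minus strand), the gene of the main cartilage collagen, was at 83.4 ± 46.6 against 4105 ± 778 CPM, a log2 fold change of -5.62 (SE 0.48). Col11a2, Col9a3, Col9a2 and the collagenase gene Mmp13 fell too, with log2 fold changes of -5.18, -5.05, -5.02 and -5.60. Osteoblast and osteocyte genes were lower in 15 of 21 cases, and 19 when adjusted over the list alone (median -2.60, camera adjusted p = 2.53e-19, and 0.165 with an estimated correlation). The bone matrix genes Spp1 (69.4 ± 23.9 against 4445 ± 101 CPM), Bglap (8.37 ± 3.92 against 497 ± 86.8 CPM) and Dmp1 (2.97 ± 2.68 against 156 ± 13.5 CPM) were among the largest falls.

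Marrow niche genes were lower in 7 of 20 cases, and 11 when adjusted over the list alone, where 2 were higher (median -0.71, camera adjusted p = 4.91e-04, and 0.553 with an estimated correlation). Feedback targets of Hedgehog, Wnt and BMP signalling were lower in 8 of 18, and 9 adjusted over the list alone, including the Wnt feedback genes Nkd2 and Notum (median -0.80, camera adjusted p = 2.23e-07, and 0.281 with an estimated correlation). Inflammatory genes were higher in 7 of 19, and 10 adjusted over the list alone (median 1.07, camera adjusted p = 3.12e-06, and 0.553 with an estimated correlation), with C3 at 28.3 ± 14.4 against 1.91 ± 0.234 CPM (SD, n = 2 each) and Ptx3 higher by 1.91 (SE 0.21) on the log2 scale. Cholesterol synthesis genes were lower as a list with 1 called of 21, and 8 adjusted over the list alone (median -0.59, camera adjusted p = 2.23e-07, and 0.553 with an estimated correlation). The mitosis list was lower with 0 of 20 members called by edgeR (median -0.46, camera adjusted p = 1.19e-05, and 0.387 with an estimated correlation). Interferon genes were higher as a list with 0 of 20 called by edgeR, and 2 adjusted over the list alone (median 0.62, camera adjusted p = 1.56e-04, and 0.387 with an estimated correlation). Of the IGF axis, Igfbp5 and Igfbp6 were higher and Stc1 lower, while the list was not called (camera adjusted p = 0.815). These calls were lost without labelled-positive replicate 2 (edgeR adjusted p = 0.375 for Igfbp5 and 0.138 for Igfbp6) or replicate 3 (0.393 for Igfbp5 and 0.0955 for Stc1). DESeq2 called 419 higher and 588 lower genes, and the authors' deposited table listed 404 and 549, sharing 219 and 363 with the edgeR calls. Counts of calls moved to 143 higher without labelled-positive replicate 2, to 1111 and 1146 without labelled-negative replicate 2, and to 2268 and 2567 without labelled-negative replicate 3, where the lone library is assumed to vary like the others.

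The knockout libraries were compared with the Sca1-positive controls (3 against 3) to ask what loss of Igf1r changes. Control libraries 2 and 3 in this comparison are the same libraries whose Ly6a ran against their label. Globin genes were lower in the knockouts, and the cause was not tested. Hba-a1 (chromosome 11, 32283511 to 32284465, plus strand), the gene of an adult alpha globin, was at 65.0 ± 15.9 CPM in knockouts and 504 ± 67.8 CPM in controls (SD, n = 3 each), a log2 fold change of -2.96 (SE 0.28, edgeR quasi-likelihood adjusted p = 0.0272). Hba-a2, Hbb-bt and Hbb-bs had log2 fold changes of -2.87, -2.76 and -2.69 (edgeR quasi-likelihood adjusted p = 0.0272, 0.0272 and 0.0345). Hba-a1 also varied among wild-type perinatal libraries outside this comparison. It was at 112 and 325 unscaled CPM in labelled Sca1-negative replicates 2 and 3, and at 257 in perinatal replicate 1 of the age table. Knockouts 1, 2 and 3 held 87.4, 53.8 and 53.3 unscaled CPM. The globin calls were lost without control 2, control 3, knockout 2 or knockout 3 (edgeR adjusted p = 0.0677 to 0.330) and against control 1 alone (0.403 to 0.475), with log2 fold changes between -3.06 and -2.52 in these fits. The separate values of these near-identical globin genes are uncertain, since the handling of reads that match both copies is not given in the sources used here. The only other called gene, Msmp, falls outside the rule for naming genes and was picked after its values were seen. It was at 340, 862 and 942 counts in controls and at 0 in all 3 knockouts, at least 302-fold lower (edgeR quasi-likelihood adjusted p = 0.0383), and it was also at 0 in perinatal replicate 1 of the age table and in the adult libraries. The bound is uncertain, since the annotation and counting behind each library are not given in the sources used here and such zeros can come from them.

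In total edgeR's quasi-likelihood test called 0 genes higher and 5 lower of 13590. At an unadjusted p under 0.05, 1647 were higher and 1316 lower, where 680 are expected over both directions. DESeq2 called 472 higher and 527 lower, limma-voom 0 and 4, and the authors' deposited table listed 436 higher and 518 lower, among them the 5 edgeR calls. The edgeR count was 0 without control 2, without control 3, without knockout 2, without knockout 3, and also with control 1 as the only control, where 14328 genes were tested. It rose to 95 higher and 211 lower without control 1, and to 1532 higher and 1471 lower without knockout 1. The Y-linked gene Ddx3y was at 0 counts in knockout 1, and at 1214 and 1507 in knockouts 2 and 3. Controls 1, 2 and 3 held 0, 129 and 0, and sex was not a term in these fits.

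Of the 33 lists 9 were called by camera, and each had an adjusted p of 0.636 with an estimated correlation. The erythroid list was lower, with 4 of 9 genes called and 7 adjusted over the list alone (median -2.69, camera adjusted p = 1.52e-07). Its median was -2.60 against control 1 alone, with a bootstrap range over genes of -2.96 to 0.16 that includes 0. This list took 0.0159% to 0.0249% of counts in knockouts and 0.125% to 0.167% in controls. Cartilage genes were lower as a list, with 0 of 21 called over all genes tested and 19 adjusted over the list alone (median -4.46, camera adjusted p = 4.34e-07). Col2a1 was at 61.0 ± 35.6 CPM in knockouts and 2702 ± 2284 CPM in controls (SD, n = 3 each), with single control levels of 131, 3642 and 4650 unscaled CPM in controls 1, 2 and 3. Against control 1 alone the cartilage median was -0.82, with a bootstrap range over genes of -0.99 to -0.21. All such ranges rest on 1 control library and hold no spread between controls. Osteoblast genes were lower as a list, with 0 of 20 called and 13 adjusted over the list alone (median -1.90, camera adjusted p = 3.49e-05). Against control 1 alone their median was only -0.04 (range -0.64 to 0.63). Fibroblast progenitor genes were higher as a list, with 0 of 20 called in either count (median 0.77, camera adjusted p = 1.25e-04). Their median against control 1 alone was only 0.08 (range -0.26 to 0.44). Feedback targets of Hedgehog, Wnt and BMP signalling were lower, with 0 of 18 called and 4 adjusted over the list alone (median -0.75, camera adjusted p = 0.00133). Against control 1 alone they were at -0.28 (range -0.75 to -0.02).

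The other called lists were also set against control 1 alone, a single library, so that the spread came from the knockouts only. Inflammatory genes were higher, with 0 of 20 called and 10 adjusted over the list alone (median 0.75, camera adjusted p = 2.34e-05). This list had a median of 0.68 against control 1 alone, with a bootstrap range over genes of -0.09 to 1.03 that includes 0. Within it Ccl2, the gene of a monocyte chemokine, was at 2431 ± 1504 CPM in knockouts and 330 ± 123 CPM in controls (SD, n = 3 each; edgeR quasi-likelihood adjusted p = 0.176). Cholesterol synthesis genes were lower, with 0 of 21 called and 10 adjusted over the list alone (median -0.72, camera adjusted p = 5.09e-06). Their median was -0.46 against control 1 alone, with a bootstrap range of -0.80 to 0.08 that includes 0. Fdps, a prenyl diphosphate synthase gene, was at 88.4 ± 16.2 against 179 ± 63.6 CPM (edgeR quasi-likelihood adjusted p = 0.181). Glycolysis genes were lower (median -0.61, camera adjusted p = 0.00825, 0 of 17 called and 1 adjusted over the list alone). Ribosomal protein genes were higher (median 0.37, camera adjusted p = 0.00291, 0 of 25 called in either count). Against control 1 alone the medians of these lists were -0.68 (range -0.95 to -0.31) and 0.25 (range 0.14 to 0.43). Neutrophil, immediate early and mitochondrially encoded genes had medians of -1.16, -0.71 and 0.57 against control 1 alone. Against all 3 controls these medians were -0.87, -0.45 and 0.31 (camera adjusted p = 0.0894, 0.0894 and 0.155), with 0 members called. The zero counts of called members here are from edgeR. Igf1 was at 921 ± 372 CPM in knockouts and 481 ± 62.7 CPM in controls, and Igf2 at 2096 ± 484 and 1572 ± 186 CPM, with neither passing edgeR's quasi-likelihood test (adjusted p = 0.184 and 0.333). The FoxO-responsive list, whose genes are repressed by insulin and IGF signalling, was not called (median -0.02, camera adjusted p = 0.493), nor was the IGF axis list (median 0.00404, camera adjusted p = 0.709).

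**Figure D3:**
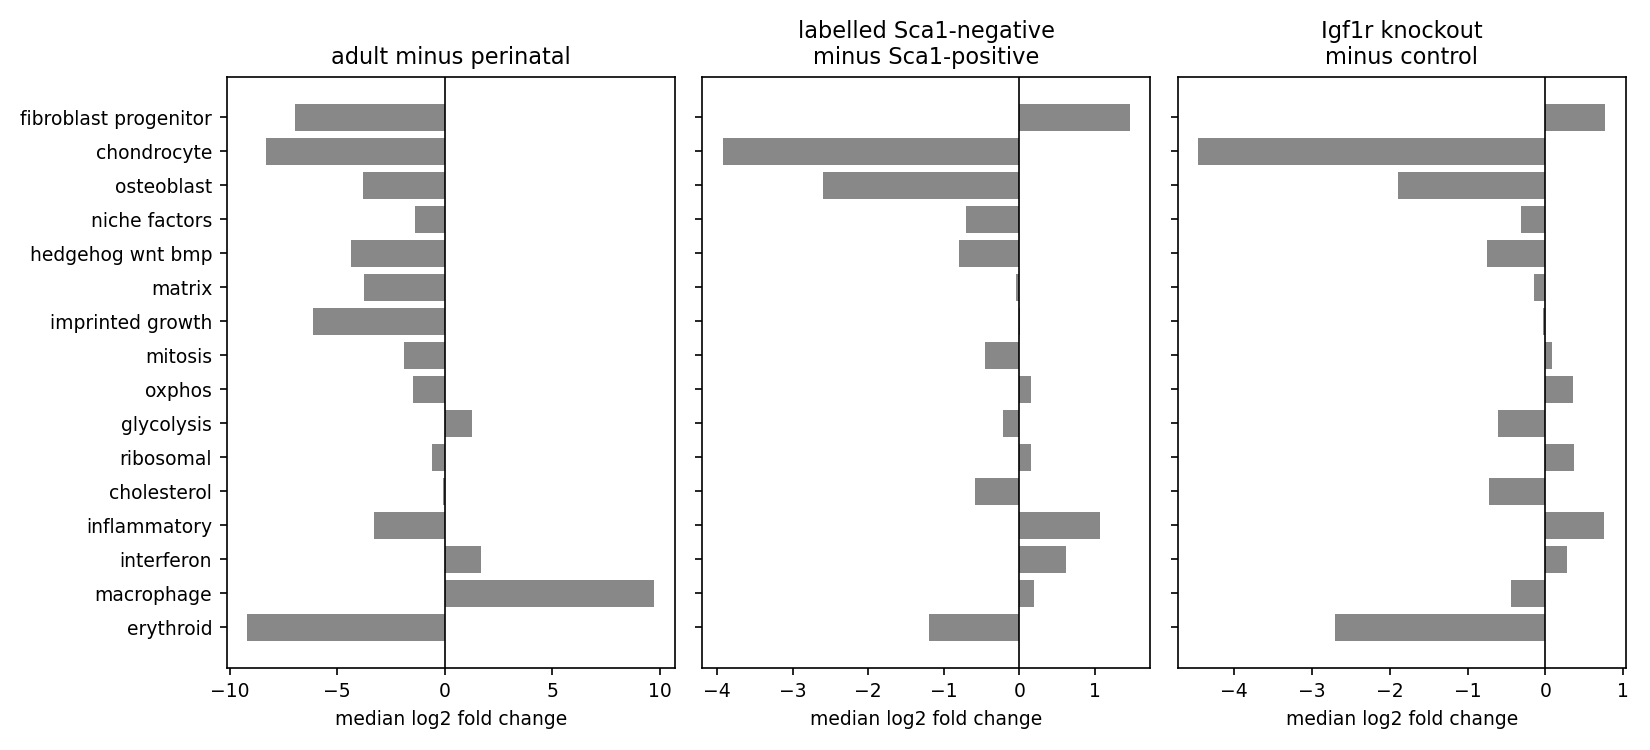
Median log2 fold change of 16 gene lists in the age, Sca1 and knockout comparisons, each on its own axis, with genes at 0 in a whole group set at their bounds. Cartilage lay at -8.31, -3.92 and -4.46 and fibroblast progenitors at -6.94, 1.46 and 0.77 in the 3 panels.

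The fold changes of the knockout were set against those of age across the 13051 genes tested in both, to ask whether loss of Igf1r moves perinatal cells toward the adult state. Genes are not independent replicates in these correlations. Pearson's r was 0.125 and Spearman's rho 0.0461, and 51.1% of genes had the same sign. Unchanged groups simulated against the same controls gave a mean r of 0.415 and 64.2% of the same sign. The covariance was 0.275, against 0.0670 in the simulations, a difference of 0.209. The 4 globin genes were lower in both comparisons, and 0 genes were higher in both. Independent lists would share 1.67 lower genes, but these lists share controls and the globin genes are near-identical copies. Those genes were also at 0 in all adult libraries, so their overlap does not measure a shared effect. Without perinatal replicate 1 of the age table r was 0.213, without knockout 1 it was 0.0764, and without shared replicate 3 it was 0.0817. The fold changes of the knockout correlated more closely with those between the libraries labelled Sca1-negative and Sca1-positive, with r = 0.709 across 13310 genes, 73.5% of the same sign and a covariance of 0.462. The simulations gave r = 0.483, 66.0% and a covariance of 0.109 for this pair, a difference in covariance of 0.353. Only Msmp was lower in both, where 0.127 would be shared by independent lists, which these are not. For knockout and age the correlation and the share of the same sign thus lay below the simulated values and only the covariance above, while for knockout and Sca1 all 3 lay above. The shared controls could not be split into parts of 2 libraries, so part of the values above the simulated ones may come from the shared controls. The simulated libraries also had a common mean, while controls 2 and 3 differed from control 1. Their median log2 differences were 3.87 for cartilage, 2.41 for osteoblast and -1.63 for fibroblast progenitor genes. The libraries labelled Sca1-negative differed from controls 2 and 3 by -3.92, -2.60 and 1.46. The simulations left out this difference and any age effect, so they cannot decide whether loss of Igf1r moved these values.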

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

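The tests without the 2 perinatal libraries low in Ly6a, without genes at 0 in a whole group, and of the shared effect without single libraries were chosen after seeing the data. The age counts kept within 1.5 times of their values under every alternative run (4733 to 5577 higher, 5162 to 6176 lower). Upper quartile factors shifted the median fold change of age by -0.129 on the log2 scale and lowered the share of higher genes from 48.5% to 44.8%. DESeq2 called 419 higher and 588 lower genes in the Sca1 comparison, and 472 and 527 in the knockout comparison, where 579 adjusted p-values were NA. Thinned counts gave 1 higher and 8 lower genes in the knockout comparison. Leaving out each library in turn gave 143 to 2268 higher and 317 to 2567 lower genes for Sca1, and 0 to 1532 higher and 0 to 1471 lower for the knockout. Without controls 2 and 3 the knockout count was 0 higher and 0 lower in edgeR, with 807 genes at an unadjusted p under 0.05. The log2 fold change of Igf1r was -2.55 with DESeq2 and -2.63 with thinned counts, both past the threshold, and -2.96 to -2.33 without single libraries. The correlation of knockout and age effects was 0.171 over genes with a mean log2 CPM of at least 5, and 0.0764 to 0.213 without single libraries. Fry gave the list of sort and target genes an adjusted p of 0.0162 downward with age, against the upward direction of camera (median 0.28, mean -0.64). For these changes the cause was not tested.

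The labels do not say that a replicate number marks a shared animal or day, so the numbers were not taken to pair the samples. Deviations of same-numbered libraries correlated at -0.019, -0.017 and 0.185 for age, 0.187, 0.118 and 0.054 for the knockout and 0.303 for the 2 Sca1 pairs, where 2 libraries per group give a single value of either sign. In the age and knockout comparisons not every library correlated best with its own number. With the number as a block, 5012 genes were higher and 5295 lower for age and 577 and 792 for Sca1. For the knockout the block fit in edgeR called 0 higher and 0 lower, with 3671 at an unadjusted p under 0.05, and the 4 globin genes had edgeR adjusted p-values of 0.0506 to 0.0591. Igf1r had a log2 fold change of -2.63 in the block fit (edgeR adjusted p = 0.0902).

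Of the 141 called named genes for age, each alternative run that tested them all kept 140 or 141, and of the 48 for Sca1 between 39 and 48 were kept. The 4 for the knockout were all kept or all lost. No named gene called in the main or the alternative fit turned its direction, and signs of genes called in neither were not compared. Fry kept 22 of 22, 5 of 13 and 1 of 9 list calls for age, Sca1 and the knockout, and an estimated correlation kept 0 in each. In the camera direction fry also called 7, 1 and 0 lists that camera did not. A joint fit over all tables was not run because replicate 1 differed between tables, tests on TPM were not needed because counts were deposited, and no correlation called for a crossed pairing. Simulated 2-fold changes were found by edgeR in 5% of cases in the knockout design and 41% in the age design, and the common biological coefficient of variation was 0.360 and 0.215.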

Other observations

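The tests of the 3 weighed patterns below were chosen after the results were seen, and the counts over other splits of the libraries were planned. Markers of several other cell types were lower in the adult libraries. All 10 tested skeletal muscle genes were lower (median log2 fold change -7.52, or -4.98 with genes at 0 at their bounds, camera adjusted p = 2.83e-04, and 0.253 with an estimated correlation), with Acta1, the gene of skeletal actin, at 11.2 ± 2.69 against 316 ± 30.7 CPM (SD, n = 3 each). Of 16 endothelial genes 13 were lower and 1 higher (median -4.80, camera adjusted p = 0.00658, and 0.423 with an estimated correlation), with Plvap at 0.174 ± 0.215 against 29.0 ± 5.06 CPM. All 7 erythroid genes were lower (median -13.66, or -9.19 at the bounds, camera adjusted p = 0.00283, and 0.442 with an estimated correlation). Of 11 neutrophil genes 8 were lower and 1 higher (median -7.43, or -4.15 at the bounds, camera adjusted p = 0.0135, and 0.279 with an estimated correlation), and the list lost its call without genes at 0 in a whole group (adjusted p = 0.246). Its exception was Csf3r, the receptor gene for granulocyte colony-stimulating factor, at 49.8 ± 2.15 against 0.568 ± 0.289 CPM. Apoe, the gene of apolipoprotein E, was the most abundant transcript of each adult library, at 19317 ± 1504 against 232 ± 91.0 CPM, and Cebpa, a transcription factor gene of adipocytes and myeloid cells, was at 248 ± 21.7 against 7.32 ± 1.13 CPM. The adipocyte list that holds both had 12 of 16 genes higher and 3 lower, and missed the threshold (median 1.05, camera adjusted p = 0.0554, and 0.400 with an estimated correlation). It passed with upper quartile factors (0.0456) and without perinatal replicate 3 (0.0363), adult replicate 1 (0.0493), adult replicate 2 (0.0389) or both perinatal libraries low in Ly6a (0.0406).

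FoxO-responsive genes were higher in 12 and lower in 6 of 20 cases in adult cells, with Pdk4, a kinase gene that acts on pyruvate dehydrogenase, at 56.2 ± 4.64 against 8.20 ± 1.82 CPM, and the list was not called (median 0.98, camera adjusted p = 0.158). Also not called with age were the lists for mitochondrially encoded genes (5 higher, 4 lower of 13, median 0.14, camera adjusted p = 0.653), cholesterol synthesis (7 and 5 of 21, median -0.06, mean 0.14, 0.866), mural cells (3 and 6 of 12, median -1.40, 0.496), osteoclasts (1 and 3 of 5, median -3.004, 0.503), megakaryocytes (3 and 2 of 5, median 0.96, 0.632), Schwann cells (1 and 4 of 6, median -2.62, 0.413) and the sort and target genes (1 and 1 of 3, median 0.28, mean -0.64, 0.963). Tagln, a smooth muscle gene of the mural list, was at 634 ± 140 CPM in adult and 36.9 ± 11.1 CPM in perinatal cells, while Cspg4, the gene of the pericyte antigen NG2, was at 4.58 ± 0.810 against 106 ± 38.1 CPM (SD, n = 3 each). Between the libraries labelled Sca1-negative and Sca1-positive, 4 lists of other cell types were called by camera with 0 members called by edgeR. These were erythroid (median -1.19, camera adjusted p = 0.00267), neutrophil (0.73, 0.00907), skeletal muscle (0.74, 0.0234) and Schwann cell genes (-1.69, 0.0234), each with an adjusted p of 0.641 with an estimated correlation. Adjusted over the list alone, 6 skeletal muscle genes were higher and 2 lower, and 5 Schwann cell genes were lower. The erythroid call was lost without labelled-negative replicate 2 (adjusted p = 0.0707), the Schwann call without labelled-negative replicate 3 (0.178), the neutrophil call without labelled-positive replicate 2 (0.101) or labelled-negative replicate 3 (0.330), and the skeletal muscle call without labelled-positive replicate 2 (0.702), labelled-positive replicate 3 (0.0600) or labelled-negative replicate 2 (0.200), or with no filter on low counts (0.0745). The other 20 lists of this comparison had camera adjusted p-values from 0.0624 to 0.978, and the 24 uncalled lists of the knockout comparison from 0.0505 to 0.836.

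Ly6a and the fibroblast progenitor genes ran against the Sca1 labels. A fault in the reads of Ly6a alone is argued against by the 12 of 19 other tested list members that were called higher in the libraries labelled Sca1-negative. A reverse relation between Sca1 protein and Ly6a transcript in these cells is argued against by the knockout libraries, also sorted as Sca1-positive, whose lowest Ly6a level was 49.4 times the highest of the labelled-positive libraries 2 and 3. Exchanged labels of the 4 libraries stay open as a candidate explanation, since the lowest Ly6a level of the 4 other Sca1-positive libraries was 425 CPM, between 13.8 CPM at most in labelled-positive libraries 2 and 3 and 659 CPM at least in the labelled-negative ones. A difference between cells with and without the marker was not tested apart from the labels, on which its direction rests.

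Macrophage genes were high in the adult libraries, although their labels gave the gate as PDGFRa+CD51+. Different gene models for adult and perinatal reads are argued against for these genes, since all 15 tested macrophage genes had reads in at least 1 perinatal library. Macrophages among the adult cells may account for the pattern, since 15 of 15 tested genes were called higher and the abundant Csf1r, C1qa and Cd68 reached 1629, 1555 and 1023 unscaled CPM in adult replicate 1, against 0.944, 0.540 and 4.32 in perinatal replicate 1. CD51 is also present on macrophages, as background, and Pdgfra, Lepr, Col1a1 and Col1a2 lay at 4.51%, 1.06%, 4.36% and 7.51% of their perinatal levels, while Cdh11, Prrx1, Cxcl12 and Pdgfrb lay at 39.2%, 40.5%, 87.2% and 126% of theirs. An effect of age on stromal cells themselves was not tested apart from this, because age, gate and cell makeup changed together. The titles of the adult samples read neg followed by a replicate number. Whether their gate and sample assignment were as labelled was not tested. The Y-linked gene Ddx3y differed too, at 39.1, 74.8 and 40.1 unscaled CPM in adult and 6.95, 7.45 and 0 in perinatal libraries.

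Cartilage genes were lower in the knockout libraries than in the 3 controls. A different cell makeup of control libraries 2 and 3 may account for most of this, since 18.4% of the median log2 fold change was kept against control 1 alone. The remaining median of -0.82 leaves an effect of Igf1r loss on cartilage genes open, because 1 control library gives no spread of its own and cannot decide it. Over all genes, the real split of the knockout and control libraries gave 5 called genes and the highest other split 1, and it was the 1 split of 10 with as many. For age the real split gave 10610 and the highest other 0, again 1 of 10, and 10 splits are too few for a share under 0.05 in either case.

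Perinatal replicate 1 of the age table differed from replicates 2 and 3 in fibroblast and cartilage genes looked up after the other values were seen, with Pi16 at 180 against 26.6 and 43.1 unscaled CPM, Dpp4 at 56.5 against 9.99 and 11.3, and Col2a1 at 72.6 against 3640 and 4646. The Y-linked gene Ddx3y had 0, 129 and 0 counts in controls 1, 2 and 3, and 0, 1214 and 1507 in knockouts 1, 2 and 3. It had 687 and 1 in the libraries labelled Sca1-negative, 103 in perinatal replicate 1 of the age table, and 675, 1269 and 538 in the adult libraries. The sex of the animals was not a term in any fit. Outside the naming rule and chosen after their values were seen, Saa3, an acute-phase gene, Cpz and Mvd came near the threshold in the knockout comparison, with log2 fold changes of 4.86, -2.34 and -1.98 (edgeR adjusted p = 0.0540, 0.0540 and 0.0561). Knockout 3 correlated least with control 1, at r = 0.853 across the log2 CPM of genes, which are not independent replicates. Lists whose median, mean or test direction differed in sign were all uncalled: cholesterol and sort genes for age, the IGF axis, imprinted, immediate early and position genes for Sca1, and the IGF axis, FoxO, mitosis, imprinted and p53 lists for the knockout.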
